A study of Rattus norvegicus with 30 samples.

How the data were processed

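Hippocampal RNA of adult Sprague Dawley rats was measured on Illumina expression arrays, with 1 rat per array. Per the labels, total RNA was extracted from the dissected hippocampus, copied into biotin-labelled cRNA and hybridised. The labels give 6 groups: female and male controls that were not exposed to predator scent, and exposed rats of each sex with a minimal or an extreme behavioural response. The values used here are the deposited processed values, which are array intensities on a log2 scale. Their range, from 6.31 to 15, and a median of 6.96 in every column were read as log2 intensity, since the log base is not given in the sources used here. The sorted values of all columns agree within 0.00119, so the deposited values had been quantile normalised between arrays. The software, the background correction and any quality filter are not given in the sources used here.

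Values were present for 29 of the 30 arrays. Male minimal responder 5 held no values, so that group had 4 rats and the others 5. A second table of array signals had column names that match no label, and its 60 columns were not used here. The analysis had been laid out, before the data were examined, for background correction and normalisation of that table. The values normalised by the authors were used in its place, as the fallback written at the same time. The filter on signal over background was therefore set on these values. A probe was kept when it lay above 7.03 on at least 5 arrays, where 7.03 is the background mode of 6.7 plus 3 times the background SD of 0.109. This kept 11888 of 22523 probes (52.8%). Of the probes kept, 8545 carried 1 gene symbol, which together named 8388 genes, and 3343 carried none. Of the 13793 symbols in the probe table, 13752 were found by gene ID in the current RefSeq table, and 0 of them differed there. An array had a given number of probes and no read depth, so the number of rats sets the precision.

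Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes). All 6 groups were fitted together without a block, with 23 residual and 5.06 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the probes kept, with a threshold of 0.05 in each comparison. Log2 fold changes are given with their SE, and group means with their SD. Exposure was the mean of the minimal and extreme responders minus the controls. A difference between the sexes was tested as an interaction, male effect minus female effect. Figures were drawn in Python 3.11.15.

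Gene lists for stress response, neurons, glia, blood vessels, neighbouring tissues and basic cell functions were fixed before the data were examined. Of the 29 lists, 25 had at least 5 genes kept and were tested with camera in limma, with the correlation between genes estimated for each list and p adjusted over the 25 lists. Camera compares a list with all other genes. The preset correlation of camera and fry, which tests whether the genes of a list move one way on balance, were alternatives. Each gene entered with its probe of highest mean intensity, and each probe without a symbol entered on its own. The 4 lists not tested were neocortex markers (4 genes kept), pituitary hormones (2), sex steroid receptors and synthesis (3) and Y-linked genes with Xist (0).

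The genes named follow a rule fixed before the data were examined. In each comparison they are the 12 largest increases and 12 largest decreases among probes past the threshold that carry a symbol. Where fewer than 10 probes passed, they are all that passed and the 10 higher and 10 lower with the smallest unadjusted p. Up to 4 members of each list were added, as were Nr3c1, Nr3c2, Fkbp5, Sgk1, Crh, Bdnf and Npy. Crhr1 and Crhr2 were in the rule and had 0 probes under those names. Genes named outside this rule are said to be so.

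A division of the arrays into 2 sets was found in the values and is not in the labels. Of 16 probes whose sorted values had a gap of at least 0.8 on the log2 scale, 8 divided the arrays in the same way, into a set A of 12 and a set B of 17. The set, the gap and every fit that uses them were chosen after the data were seen. Every comparison was refitted with the set as a block and within set B. The fits were tested on simulated data at the same sample sizes. The simulated noise was independent between probes, and 200 probes were changed by 0.4, 0.7 or 1. Without a set effect, limma called 70.1%, 89.6% and 98.5% of them in the contrast of extreme and minimal female responders. With set effects simulated and the set as a block, it called 56.7%, 92.5% and 100%. In the same contrast of males it called 47.8%, 88.1% and 97% with the block. Other alternatives were no filter, a stricter filter, each sex alone, array weights, replicate number as a block, cyclic loess after the deposited normalisation, a variance trend with a robust prior, residual principal components as covariates, and leaving out each rat. Random splits of the rats, 100 or all where fewer existed, gave the counts expected with no group difference.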

Results

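Gene expression was measured in the hippocampus of 29 rats, of which 15 were female and 14 male. There were 5 rats in each of female controls, female minimal responders, female extreme responders, male controls and male extreme responders, and 4 male minimal responders. The series asks which hippocampal transcripts differ after exposure to predator scent, and which differ between exposed rats with an extreme and a minimal behavioural response, in each sex. Of the 11888 probes tested, all carry an intensity on the log2 scale, so 1 unit is a doubling. Every array had 10332 probes above background, a number fixed by the normalisation between arrays. Male extreme responder 4 stood apart, with a median correlation to the other arrays of 0.964.

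The values of 8 probes divided the rats into 2 sets that crossed sex and the control and minimal groups. *Rpl37l1*, *Rpl7* and *Rpl23*, which encode proteins of the large ribosomal subunit, were far higher in the 12 rats of set A than in the 17 of set B, and the other 5 probes carried no symbol. Ribosomal proteins as a list did not pass between the sets: 18 of 63 passed, 12 higher and 6 lower in A (adjusted p = 0.886 with an estimated correlation). *Rpl37l1* had a mean of 12.3 ± 0.36 (SD) in set A and 9.6 ± 0.29 in set B, and the lowest rat of A (11.32) lay above the highest of B (10.13). *Actb*, the gene of beta-actin, was lower in set A on each of its 3 probes (set A minus set B −1.31, −1.08 and −0.60). *Rims1*, which organises the presynaptic release site, was lower as well (−0.98). It was named outside the rule, which does not cover the sets. With limma, 2249 probes (18.9%) differed between the sets, 1025 higher and 1224 lower in A, with a median size of 0.27. Set A held 3 of the 5 rats in each of the female control, female minimal and male control groups, 3 of the 4 male minimal responders and 0 of the 10 extreme responders. Contrasts with extreme responders are therefore partly confounded with the set, and each is given below also with the set as a block. Counts within set B are given only for comparisons without male minimal responders, of which set B held 1.

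**Figure D1:**
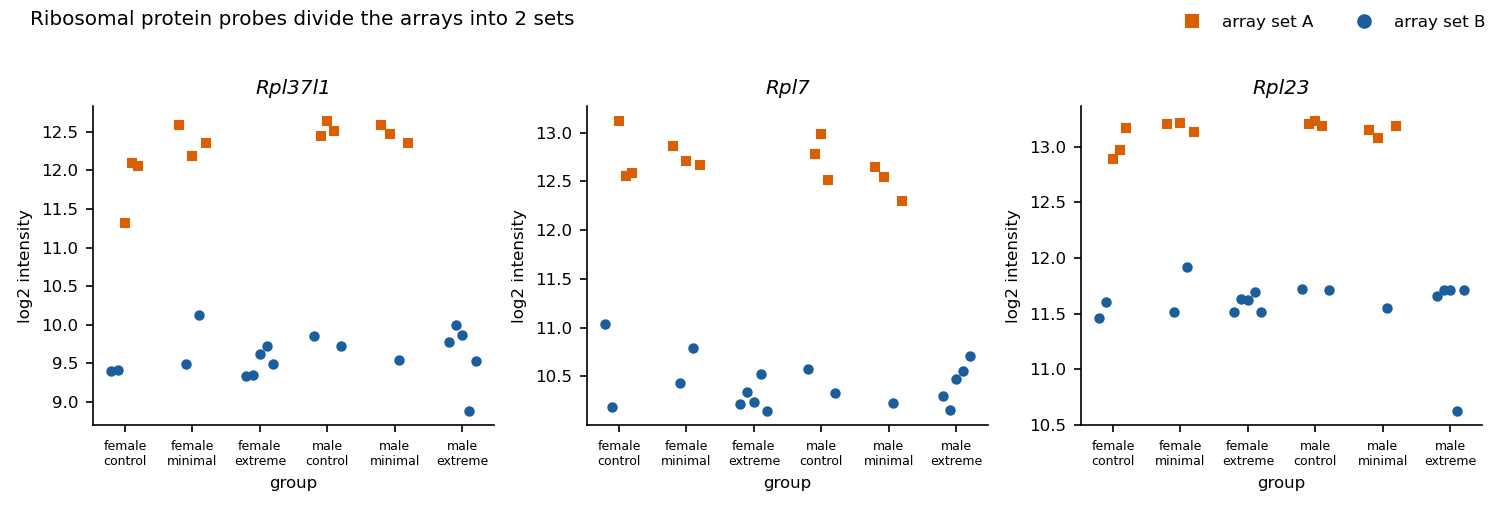
Log2 intensity of *Rpl37l1*, *Rpl7* and *Rpl23* in each rat, by group, with the 12 rats of set A as squares and the 17 of set B as circles. No rat lies between the sets, and all 10 extreme responders are in set B.

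In exposed females, genes induced by glucocorticoids and genes induced within minutes by neuronal activity were higher than in control females. *Ddit4*, a glucocorticoid-induced inhibitor of the mTOR pathway, rose by 0.78 ± 0.13 (adjusted p = 0.0306), from 9.88 ± 0.22 (SD, n = 5) in controls to 10.36 ± 0.15 in minimal and 10.96 ± 0.07 in extreme responders. All 10 exposed females lay above the highest control. Of 20 glucocorticoid-responsive genes, 15 had a higher value, with a median log2 fold change of 0.15. Over all probes 1 of them passed, and 8 did when adjusted over the list alone, among them *Sgk1* (0.63 ± 0.16), a kinase induced by glucocorticoids, *Gpd1* (0.72 ± 0.16) and *Nfkbia* (0.64), the inhibitor of NF-κB. Of 18 immediate early genes, 15 had a higher value, with a median of 0.27. Over all probes 0 of them passed and 10 passed when adjusted over the list alone, among them *Arc* (0.99 ± 0.21), which acts in synaptic plasticity, *Junb* (0.73) and *Fos* (0.46). Both lists rose against all other genes (adjusted p = 0.0464 for each with an estimated correlation). These values average minimal and extreme responders, and those of the extreme responders were larger. Against controls the glucocorticoid list had a median of 0.08 in minimal and 0.23 in extreme responders, and the immediate early list 0.18 and 0.36. *Sgk1* was at 0.20 ± 0.19 and 1.07 ± 0.19. *Fkbp5*, also on the glucocorticoid list, was at −0.08 ± 0.12 for exposure. Oligodendrocyte markers had a median of 0.20 with 12 of 13 higher (0.55, or 0.00225 with the preset correlation), and choroid plexus markers of 0.24 with 8 of 10 higher (0.825 and 0.437).

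*Ddit4* was the only probe of 11888 past the threshold for exposure in females, although 1208 had an unadjusted p under 0.05, against 594 expected by chance. Its call held in 19 of 29 leave-outs and ended without female control 1, 3, 4 or 5, female minimal 2 or 5, or female extreme 2, 3, 4 or 5, and with the replicate number as a block (0.78, adjusted p = 0.0742). The probes next to it did not pass, among them *Klf2* (0.45 ± 0.09, adjusted p = 0.0569), *Pacsin1* (0.51 ± 0.10, 0.0569), *Per1* (0.43 ± 0.09, 0.0677) and *Slc41a1* (−0.30 ± 0.07, 0.0914). With the set as a block, 26 probes passed (16 higher, 10 lower), including *Ddit4* (0.67), *Nfkbia* (0.76), *Arc* (1.05), *Junb* (0.82) and *Per1* (0.45). The glucocorticoid list then had a median of 0.17 (adjusted p = 0.0295) and the immediate early list 0.30 (0.0592, no longer past the threshold). Within set B, 0 probes passed with limma (832 unadjusted), and the medians of both lists were 0.26 and 0.21. The calls of both lists stood close to the threshold: leaving out any of 20 of the 29 rats ended them, and the exceptions were female control 3, female minimal 4, female extreme 4 and 5, male minimal 2 and 4, and male extreme 3, 4 and 5.

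Neither stress list passed in exposed males. Their glucocorticoid-responsive genes had a median of 0.05 and their immediate early genes of 0.06 (adjusted p = 0.774 for both with an estimated correlation). Neither list passed for the sex difference in the exposure effect either. That difference, male minus female, had a median of −0.17 for the glucocorticoid list and −0.20 for the immediate early list. With the set as a block, camera with an estimated correlation gave an adjusted p of 0.449 and 0.481. *Ddit4* went from 10.14 ± 0.36 in male controls to 10.49 ± 0.45 (n = 4) in minimal and 10.3 ± 0.17 in extreme responders. The genes with the smallest p were lower in exposed males and did not pass: *Slc15a4*, a lysosomal peptide transporter (−0.40 ± 0.08), *Rab24*, a small GTPase linked to autophagy (−0.35 ± 0.07), *Rps10* (−0.37 ± 0.08) and *Pdyn*, the precursor of dynorphin (−0.65 ± 0.15). Of 63 cytoplasmic ribosomal proteins, 55 had a lower value (median −0.14, adjusted p = 0.477 with an estimated correlation), and 5 were lower when adjusted over the list alone. Of 13 interneuron markers, 12 had a higher value (median 0.24, adjusted p = 0.247). With limma 0 probes passed (smallest adjusted p = 0.102, 1010 unadjusted), and 0 passed with the set as a block (1238 unadjusted).

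Over both sexes, 13 probes passed for exposure, 9 higher and 4 lower. Among them, *Ddit4* (0.52), *Adgrb2* (0.44), *Tob2* (0.41), an antiproliferative factor, *Pacsin1* (0.38), which acts in synaptic vesicle endocytosis, and *Kcnj11* (0.25), the pore of ATP-sensitive potassium channels, rose. *Cxcl12*, a chemokine (−0.43), *Ovca2* (−0.36) and *Slc41a1*, a magnesium transporter (−0.24), fell. The unadjusted count was 1032. In the blocked fit 30 probes passed, 16 higher and 14 lower, 9 of them shared. The count of 13 fell to 0 without female control 1 or 4, female minimal 5, female extreme 3, male control 2 or 3, or male minimal 4. It was within 1.5 times of 13 only without female control 2, female minimal 4, male minimal 2 or male extreme 3, 4 or 5, and from 1 to 8 without any other rat.

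Genes of both stress lists were among the 119 probes that passed between female extreme responders and controls. *Sgk1* rose by 1.07 ± 0.19 (adjusted p = 0.00437), from 11.71 ± 0.34 to 12.78 ± 0.21 (SD, n = 5 each), and every extreme responder lay above every control. *Ddit4* rose by 1.08 ± 0.15 (0.000434), *Nfkbia* by 0.87 ± 0.17 (0.00874), *Gpd1* by 0.82 ± 0.19 (0.0237), the clock gene *Per1* by 0.66 ± 0.11 (0.00129) and *Errfi1*, a feedback inhibitor of the EGF receptor, by 0.57 ± 0.10 (0.00537). These were the 6 of 20 glucocorticoid-responsive genes that passed, and 10 passed when adjusted over the list alone. *Fkbp5*, of the same list, had a lower value and did not pass (−0.24 ± 0.13, adjusted p = 0.463). Of the immediate early genes, *Arc* (1.21 ± 0.24) and the AP-1 subunit *Junb* (0.95 ± 0.21) rose, and 10 of 18 rose when adjusted over the list alone. *Cnih2*, an auxiliary subunit of AMPA receptors (1.23 ± 0.29), *Sik1*, a salt-inducible kinase (0.71 ± 0.13), *Adgrb2* (0.93 ± 0.14), *Tob2* (0.88 ± 0.13), *Marcksl1* (0.73 ± 0.14), and the glutamate receptor subunit *Grin2c* (0.50) also rose.

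**Figure D2:**
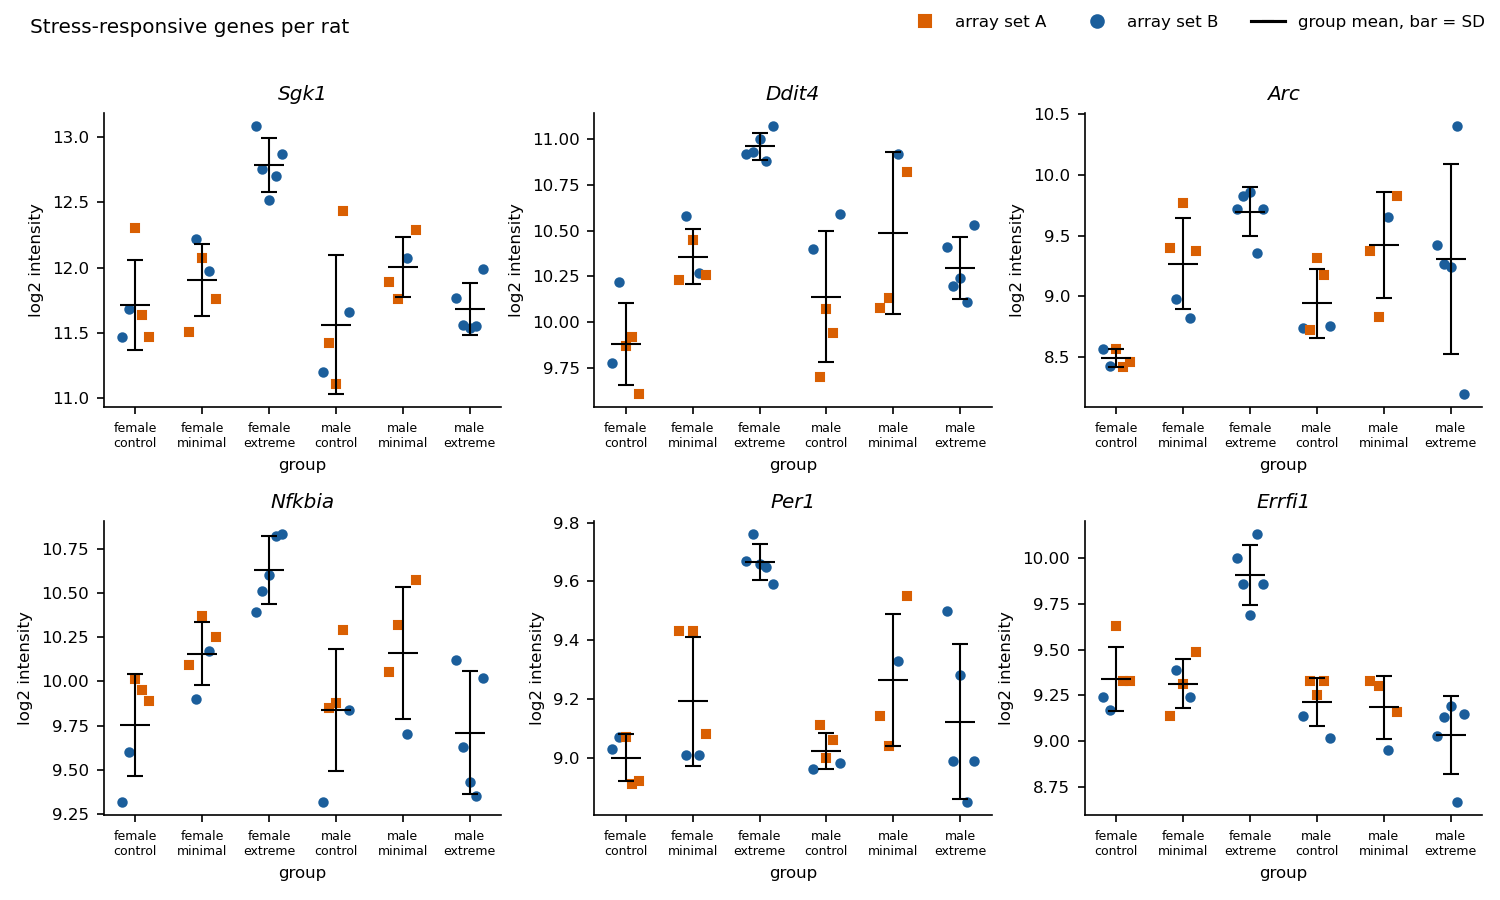
Log2 intensity of *Sgk1*, *Ddit4*, *Arc*, *Nfkbia*, *Per1* and *Errfi1* in each rat, by group, with horizontal lines at the group mean and bars of 1 SD. For all 6 genes, the 5 female extreme responders lie above the highest female control.

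In female extreme responders against controls, *Eef1a1*, a translation elongation factor, fell by 1.20 ± 0.22 (adjusted p = 0.00496) and *Slc41a1* fell by 0.54 ± 0.08 (0.000434). *Ndufa8*, a subunit of respiratory complex I (−0.46), *Mpv17*, a mitochondrial inner membrane protein (−0.48), *Mrps17*, of the mitochondrial ribosome (−0.52), *Pdpn* (−0.48), and the interferon regulatory factors *Irf3* (−0.46) and *Irf1* (−0.43) fell as well. Of 59 oxidative phosphorylation subunits, 43 had a higher value (median 0.09), 0 rose and only *Ndufa8* fell. Of 10 inflammatory genes only *Irf1* passed, and of 10 striatum markers only the adenosine receptor *Adora2a* (−0.42). Oligodendrocyte markers had a median of 0.36, with 12 of 13 higher, 0 past the threshold over all probes and 4 when adjusted over the list alone (adjusted p = 0.477 with an estimated correlation).

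For female extreme responders against controls, 119 probes passed, 69 higher and 50 lower, with 1571 at an unadjusted p under 0.05. As lists, the glucocorticoid-responsive genes had a median of 0.23 (adjusted p = 0.0501 with an estimated correlation) and the immediate early genes of 0.36 (0.0838), so neither passed. When blocked by set, 189 probes passed, 106 higher and 83 lower, 74 of them shared, and the glucocorticoid list had a median of 0.30 (0.0141). The blocked values were 1.08 for *Sgk1*, 0.87 for *Ddit4*, 1.33 for *Arc* and 1.12 for *Nfkbia*, and −0.92 for *Eef1a1*. The calls of *Cnih2* (0.92, adjusted p = 0.0939), *Mrps17* (−0.49, 0.074), *Mpv17* (−0.38, 0.0729), *Irf3* (−0.33, 0.081), *Irf1* (−0.37, 0.081) and *Adora2a* (−0.30, 0.114) ended with the block. Within set B, where 2 controls remained, 2 probes passed with limma (1071 unadjusted). The 119 became 60 and 64 without female control 3 and 4, 76, 73, 67 and 72 without female extreme 2, 3, 4 and 5, 183 without female control 2 and 211 without male extreme 4.

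**Figure D3:**
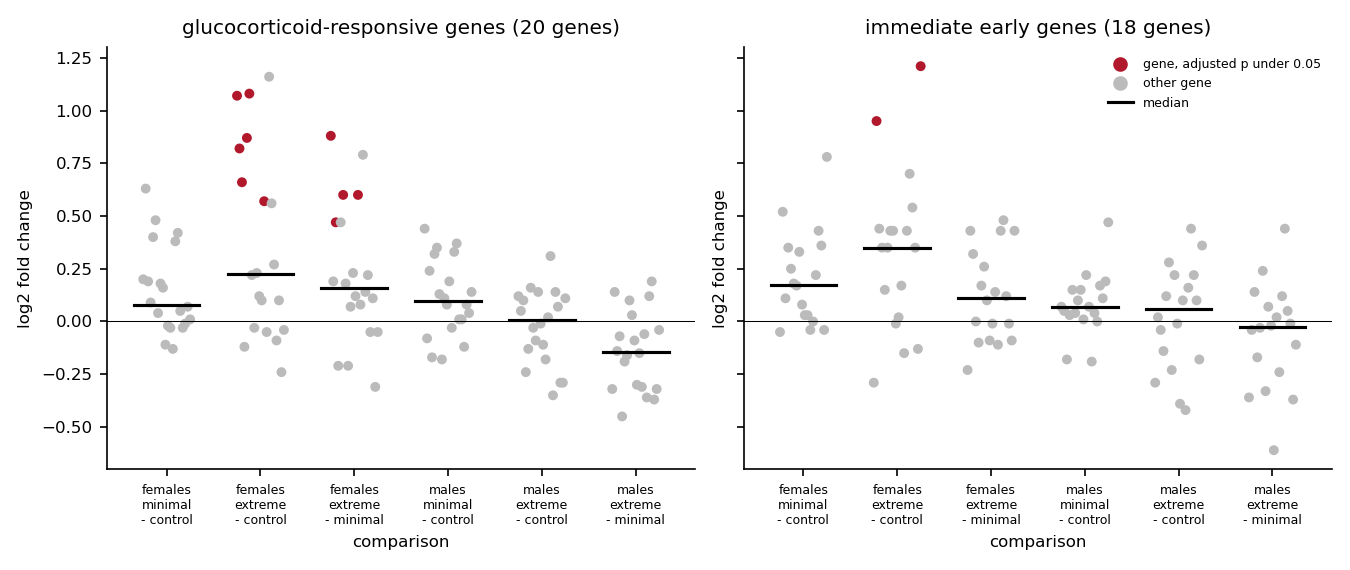
Log2 fold changes of 20 glucocorticoid-responsive genes and 18 immediate early genes in 6 comparisons, with a point per gene, red where the gene passed over all probes, and a line at the median. Red points appear in 2 of the female comparisons on the left, extreme against control (6 genes) and extreme against minimal (4 genes), and in extreme against control females on the right (2 genes).

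Among exposed females, *Sgk1* rose from minimal to extreme responders by 0.88 ± 0.19 (adjusted p = 0.00822), with all 5 extreme responders above the highest minimal responder. *Errfi1* rose by 0.60 (0.0019), *Ddit4* by 0.60 (0.0251) and *Per1* by 0.47 (0.0114). These were 4 of 20 glucocorticoid-responsive genes, and 6 rose and 1 fell when adjusted over the list alone (median 0.16). *Fkbp5*, of the same list, was lower and did not pass over all probes (−0.31 ± 0.13, adjusted p = 0.201). *Cd93*, a receptor of endothelial cells (0.80 ± 0.15), *Plat*, tissue plasminogen activator (0.79 ± 0.11), the endothelial receptor *Tie1* (0.40), *Nfil3*, a repressor of transcription (0.68 ± 0.13), and *Tmem252* (0.63 ± 0.08) rose. Of 9 endothelial and pericyte markers, 8 had a higher value and 1 passed, or 3 when adjusted over the list alone (median 0.16). The oligodendrocyte genes *Olig1* (0.55) and *Cnp* (0.52) rose, 2 of 13 markers of that cell type, of which 11 had a higher value (median 0.26).

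The falls between extreme and minimal female responders were more numerous. *Eef1a1* fell by 1.01 ± 0.22 (adjusted p = 0.00816), *G0s2*, an inhibitor of triglyceride lipase, fell by 0.85 ± 0.13 (0.000352) and *Rab24* fell by 0.63 ± 0.08 (7.27e-05), from 11.64 ± 0.12 to 11.01 ± 0.09. *Ccn2*, a matricellular growth factor (−0.94 ± 0.23), *Hapln2*, of the matrix at nodes of Ranvier (−0.69 ± 0.15), *Ppt2*, a lysosomal thioesterase (−0.69 ± 0.09), and *Acaa1a*, of peroxisomal β-oxidation (−0.65 ± 0.10), fell. Of 11 clock genes, *Per2* (−0.69 ± 0.15), *Cry1* (−0.53) and *Dbp* (−0.28) fell while *Per1* rose, so the list had a median of 0.13, a mean of −0.04 and camera's direction was down (adjusted p = 0.967). Among 18 genes of heat shock and the unfolded protein response, *Ddit3* (−0.45), *Xbp1* (−0.40) and *Dnajb1* (−0.37) fell and *Pdia3* (0.33) rose. Of 63 ribosomal proteins 46 had a lower value (median −0.18), 6 fell, among them *Rpl31* (−0.41), *Rpsa* (−0.38) and *Rpl7a* (−0.35), and 15 fell when adjusted over the list alone. *Irf1* (−0.54), *Ndufa8* (−0.51), *Ndufv2* (−0.30) and *Nrgn*, a postsynaptic calmodulin-binding protein (−0.38), fell too.

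In this comparison 450 probes passed, 162 higher and 288 lower, with 2193 unadjusted. The count was 222 and 279 without female minimal 5 and 3, and 227, 262 and 299 without female extreme 1, 2 and 4. No list passed with an estimated correlation, and adjusted p was 0.152 for immature neuron and progenitor markers, of which all 9 had a higher value (median 0.16). It was 0.471 for glucocorticoid-responsive genes, endothelial and pericyte markers and glutamate receptors (median 0.11), 0.475 for ribosomal proteins and for heat shock and unfolded protein response (median −0.15), and 0.496 for oligodendrocyte markers. In the blocked fit 388 probes passed, 166 higher and 222 lower, and 226 of them were shared. The blocked values were 0.89 for *Sgk1*, 0.99 for *Cd93*, 0.82 for *Plat*, −0.73 for *Eef1a1*, −0.63 for *Rab24* and −0.62 for *Per2*. The calls of *Ddit4* (0.39, adjusted p = 0.117), *Cnp* (0.43, 0.13), *Ccn2* (−0.77, 0.0695), *Cry1* (−0.34, 0.133), *Dbp* (−0.26, 0.0727), *Ddit3* (−0.36, 0.101) and *Xbp1* (−0.26, 0.129) ended with the block. The blocked median of the clock list was −0.16, against 0.13 without a block. Within set B, with 2 minimal responders, 0 probes passed with limma (1386 unadjusted).

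Male extreme responders differed from controls at 74 probes, 20 higher and 54 lower. *Pdyn*, made by dentate granule cells, fell by 0.77 ± 0.17 (adjusted p = 0.0359), from 8.46 ± 0.32 to 7.69 ± 0.33 (SD, n = 5 each). *C1ql2*, a synaptic organiser of granule cells, fell by 0.84 ± 0.20 (0.0467), and it was 1 of 5 dentate granule cell markers to pass (median −0.07). The ligands *Wnt4* (−0.79 ± 0.19) and *Cxcl12* (−0.68 ± 0.14), *Slc15a4* (−0.53 ± 0.09) and *Manf*, a factor induced by endoplasmic reticulum stress (−0.50 ± 0.09), fell. *Rps10* (−0.55 ± 0.09) and *Rplp0* (−0.35) fell, 2 of 63 ribosomal proteins, of which 49 had a lower value (median −0.17) and 6 fell when adjusted over the list alone. *Stmn1*, which destabilises microtubules, rose by 0.83 ± 0.19 (0.0367), and all 5 extreme responders lay above the highest control. *Kcnj11* (0.38 ± 0.08), the mitochondrial pyruvate carrier *Mpc1* (0.36) and the ATP synthase subunit *Atp5f1b* (0.34) rose, while the complex I subunit *Ndufv2* (−0.36) fell.

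Of 20 glucocorticoid-responsive genes, 10 had a higher and 10 a lower value in male extreme responders against controls (median 0.01), and 0 passed. *Sgk1* differed by 0.12 ± 0.19 and *Ddit4* had means of 10.14 and 10.3. Interneuron markers had a median of 0.33, with 12 of 13 higher and 0 past the threshold over all probes, or 1 when adjusted over the list alone (adjusted p = 0.404 with an estimated correlation). The 74 probes stood beside 1962 at an unadjusted p under 0.05. When blocked by set, 57 passed, 25 higher and 32 lower, and 20 of them were shared. The blocked values were −0.93 for *Pdyn*, −0.47 for *Rps10*, −0.46 for *Manf* and 0.44 for *Kcnj11*. The calls of *C1ql2* (−0.78, adjusted p = 0.0936), *Wnt4* (−0.75, 0.0873), *Cxcl12* (−0.64, 0.0575), *Stmn1* (0.85, 0.0563) and *Atp5f1b* (0.29, 0.0532) ended with the block. Within set B 0 probes passed with limma (1182 unadjusted). The 74 became 22, 22 and 6 without male control 2, 3 and 4, and 47, 18 and 124 without male extreme 2, 4 and 5. With each sex fitted alone 0 passed.

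Between extreme and minimal male responders, 9 probes passed, of which 8 carried a symbol. *Marcksl1* (0.75 ± 0.14), *Zfp638* (0.50 ± 0.10), the lysosomal thioesterase *Ppt1* (0.50 ± 0.10) and *Cdk2ap1* (0.45 ± 0.09) rose. *Pakap* (−0.43 ± 0.08), *Mnat1*, of the CDK-activating kinase (−0.38 ± 0.07), *Nus1* (−0.37 ± 0.07) and *Stim1*, the calcium sensor of the endoplasmic reticulum (−0.34 ± 0.07), fell. *Stmn1* did not pass (0.91 ± 0.20, adjusted p = 0.0603). The glucocorticoid-responsive genes had a median of −0.15, with 15 of 20 lower, and choroid plexus markers of −0.47, with all 10 lower (adjusted p = 0.773 for both with an estimated correlation). There were 4 males in the minimal group and 1799 probes at an unadjusted p under 0.05. The set as a block ended all 9 calls and gave 4 other probes. Set B held only 1 male minimal responder, so no count within it is given for this comparison. Without male minimal 3 the count was 101, and without male minimal 1 or 4, male extreme 1, 2 or 4, or female minimal 2 it was 0. It was 15, 17 and 35 without male control 4, male extreme 3 and male extreme 5, and from 1 to 5 without female control 3 or 5, female extreme 1, 2 or 3, male control 1, 2 or 3, or male minimal 2.

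Minimal responders did not differ from controls at the threshold in either sex. In females 0 of 11888 probes passed with limma (1314 unadjusted, smallest adjusted p = 0.0891). The nearest were *Ppt2* (0.49 ± 0.09), *Ece1*, the endothelin-converting enzyme (0.51 ± 0.11), and *Fabp7*, a fatty acid binding protein of radial glia and astrocytes (−0.74 ± 0.16). *Rab24* was at 0.34 ± 0.08 and *Dnajb1* at 0.31 ± 0.07. Glucocorticoid-responsive genes had a median of 0.08 in these females. Immediate early genes had a median of 0.18 with 14 of 18 higher, 0 past the threshold over all probes and 3 when adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). In the blocked fit 6 probes passed, including *Ppt2* (0.49, adjusted p = 0.00163), *Ssbp4* (0.36) and, outside the rule and named after its value was seen, *Lpcat3* (−0.36). In males 0 passed (504 unadjusted, fewer than the 594 expected by chance), and the GABA receptor subunit *Gabbr2* was at 0.49 ± 0.13 (0.922). The block gave 1 probe in males. Within set B limma called 0 in females (783 unadjusted), while no count is given for males, which had 1 minimal responder there. Within set A limma called 1 in females and 2 in males (1247 and 520 unadjusted).

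Over both sexes, extreme and minimal responders differed at 945 probes, 394 higher and 551 lower (2831 unadjusted). *Rpl37l1* fell by 1.99 ± 0.49, *Rpl7* fell by 1.55 ± 0.41 and *Rpl23* fell by 1.13 ± 0.29, and with the set as a block they were at −0.21, −0.06 and −0.12, which follows from their part in defining the sets. *Actb* rose by 0.70 and turned to −0.03 with the block. The myelin gene *Cldn11* rose by 0.75, was at 0.05 with the block and turned to −0.03 within set B. *Slc48a1*, a haem transporter (0.80, blocked 0.26), *Atp5pf* (0.73, blocked 0.20) and *Hspe1*, a mitochondrial chaperonin (−0.56, blocked −0.11), also lost the call. With the block 244 probes passed, 99 higher and 145 lower, and 143 of them were shared, which is 15.1% of the 945. No count within set B is given, since it held 1 male minimal responder. The 945 became 609 without male minimal 4.

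The genes below passed over both sexes in extreme against minimal responders with and without the block. *Marcksl1* (0.73 ± 0.10, blocked 0.48), *Stmn1* (0.62 ± 0.14, blocked 0.64), the cytosolic chaperone *Hsp90aa1* (0.41, blocked 0.57) and *Tie1* (0.29, blocked 0.36) rose. *Necab2*, a neuronal calcium-binding protein (−0.66 ± 0.12, blocked −0.60), *G0s2* (−0.60 ± 0.09, blocked −0.48), *Irf1* (−0.40, blocked −0.34) and *Rpl6* (−0.20, blocked −0.30) fell. *Fkbp5*, a chaperone that restrains the glucocorticoid receptor and is itself induced by glucocorticoids, fell by 0.32 ± 0.10 (adjusted p = 0.0418), and its call ended with the block (−0.30, 0.182).

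**Figure D4:**
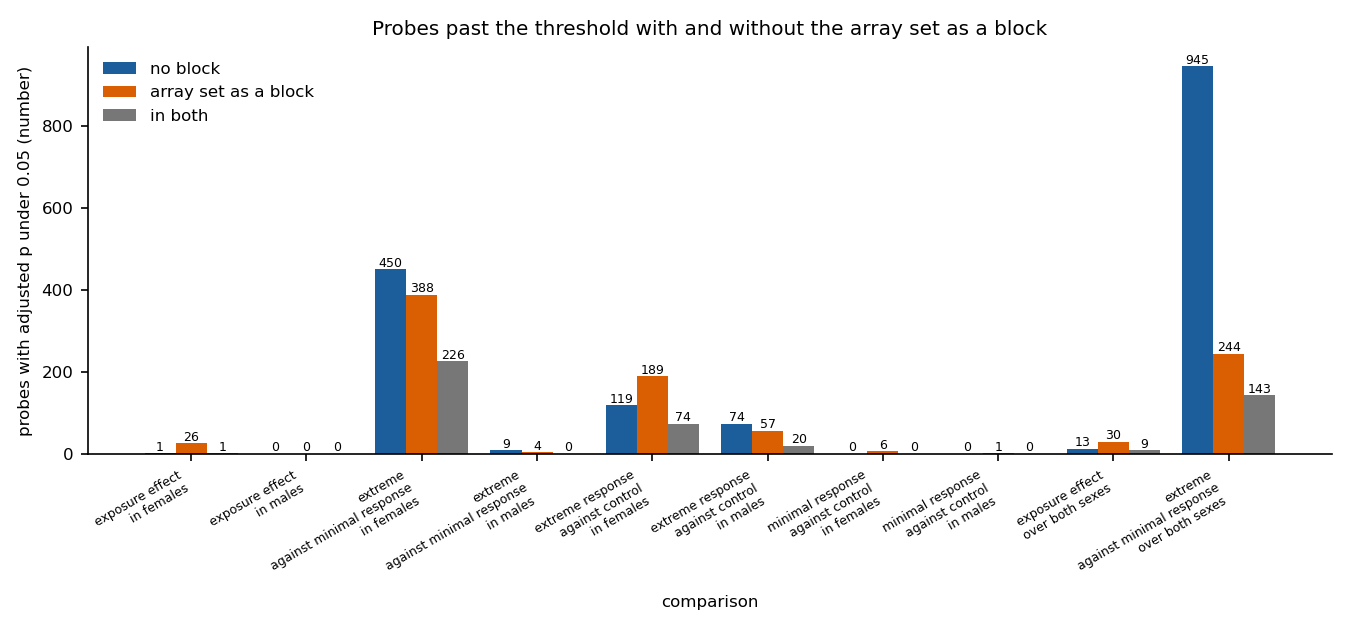
Number of probes with an adjusted p under 0.05 in 10 comparisons, without a block, with the array set as a block, and in both fits. The contrast of extreme and minimal responders over both sexes falls from 945 to 244, of which 143 are shared.

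Whether the sexes differ in their responses was tested directly, and 0 probes passed with limma for exposure (1150 unadjusted) or for extreme against minimal response (932 unadjusted). In the latter, *Sgk1* differed by −1.20 ± 0.27 (male minus female effect, adjusted p = 0.156), *Nfil3* by −0.87 ± 0.19 (0.141), *Errfi1* by −0.75 ± 0.15 (0.08) and *Tmem252* by −0.65 ± 0.12 (0.0682). *Per2* was at 0.94 ± 0.22 (0.157) and *Klf5* at 1.62 ± 0.40 (0.179). When blocked by set, 4 probes passed, 3 of them with a symbol: *Errfi1* (−0.72), *Tmem252* (−0.64) and *St3gal4* (0.70), each at an adjusted p of 0.0448. The glucocorticoid-responsive genes had a median difference of −0.36, with 16 of 20 lower (adjusted p = 0.118 with an estimated correlation, 0.104 with the block). For exposure *Csgalnact1* came nearest (0.56 ± 0.11, adjusted p = 0.165, blocked 0.57 and 0.0534). No count within set B is given for either difference, since that set held 1 male minimal responder.

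Female and male effects were compared across 11731 values, from 8388 named genes and 3343 probes without a symbol. The effects of exposure were unrelated in these data (r = 0.03), and 92 of 100 relabellings of the rats gave as large an r (permutation p = 0.92). The effects of extreme against minimal response had r = 0.44 between the sexes (permutation p = 0.03), and 62.4% of these values had the same sign. With the set as a block r was 0.36 (permutation p = 0.05, no longer under the threshold). Within set B r was 0.30, but there the male effect rests on 1 minimal responder, and no relabelling was made. Genes are not independent replicates, so no p over genes is given. The effects of extreme and of minimal response against their shared controls had r = 0.32 in females and 0.20 in males (0.40 and 0.32 with the block). Simulated groups with no effect that share controls gave 0.50 and 0.47, and with the controls split between both effects the median r was 0.02 and −0.03 over 20 splits.

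The corticosteroid receptors and stress peptides fixed as targets did not pass in any comparison. In female extreme responders against controls, the glucocorticoid receptor gene *Nr3c1* was at 0.15 ± 0.09 (adjusted p = 0.492) and neuropeptide Y (*Npy*) at 0.61 ± 0.27 (0.312). In male extreme responders against controls, the mineralocorticoid receptor gene *Nr3c2* was at −0.32 ± 0.13 (0.218) and *Crh* at 0.20 ± 0.11 (0.343). *Bdnf* was at −0.13 ± 0.09 for exposure in females (0.701). With the set as a block these were 0.16 for *Nr3c1*, 0.12 for *Npy*, −0.36 for *Nr3c2*, 0.20 for *Crh* and −0.19 for *Bdnf*.

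Males and females differed at 25 probes, 11 higher and 14 lower in males (1308 unadjusted). The X-linked translation factor gene *Eif2s3* fell by 0.39 ± 0.04 from females to males (adjusted p = 2.61e-05), with female group means of 7.96 to 8.01 and male ones of 7.55 to 7.62. The X-linked *Pcdh19*, a protocadherin (−0.39 ± 0.08), *Glra2*, a glycine receptor subunit (−0.46 ± 0.10), and *Pbdc1* (−0.35 ± 0.06) were lower in males. So were *Ptpro*, a receptor phosphatase (−0.53 ± 0.07), and catalase (*Cat*, −0.39 ± 0.08). *Errfi1* was lower too (−0.38 ± 0.06), mainly through the extreme responders, with means of 9.91 in females and 9.03 in males. Its female and male means were 9.34 and 9.22 in controls, and 9.31 and 9.19 in minimal responders. *Tnnc2* (0.72 ± 0.12), the taurine transporter *Slc6a6* (0.35 ± 0.07) and *Aadat*, of kynurenine metabolism (0.33 ± 0.05), were higher in males. All 25 passed with the set as a block, which gave 56. The 25 became 79 without male extreme 4 and 48 without female minimal 1.

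The counts of lists with camera's preset correlation were 5 for exposure in females, 2 for exposure in males, 7 for extreme against minimal response in females and 1 in males. With an estimated correlation the glucocorticoid-responsive and immediate early lists for exposure in females held, and none of the others did. Fry, which asks whether a list moves one way on balance, passed 2, 0, 1 and 0 lists in these comparisons, the 1 being the immature neuron and progenitor markers. Elsewhere fry passed 2 lists for extreme against control in females. It passed 1 for the sex difference in exposure, 3 for that in extreme against minimal response, and 0 in the remaining comparisons. The preset correlation passed 2 to 7 lists in each of these other comparisons, and the estimated correlation 0.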

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

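The tests of the array set, of a single rat, of a second set and of *Rps9* were chosen after the results were seen, while that of blood vessel cells was laid out before its result was seen. Chance alone puts a rat far from its group in about 1 of 20 groups. In 5 of 78 groups a rat lay far from the others of its group, by a gap that was large for the range of the group, against 3.9 expected. The 78 include the number of probes above background in each group. It was 10332 on every array and could not be flagged, so fewer than 3.9 were expected. *Sgk1* in female control 3 was 12.3, against 11.68 in the next control. *Arc* in female extreme 4 was 9.36, with the nearest at 9.72. *Pdyn* in male control 3 was 7.91, with the nearest at 8.49. *Eif2s3* in male minimal 1 was 7.84, and the nearest was 7.56. The median correlation of male extreme 4 with the other arrays was 0.964, and the next of its group was 0.9845.

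Glucocorticoid-responsive and immediate early genes were higher in exposed than in control females, with a median of 0.146 for the glucocorticoid list. The array set as a block left that median at 0.174, so the set is argued against as its cause. A larger share of blood vessel cells is argued against too, since the median was 0.152 with the mean of 9 endothelial and pericyte markers as a covariate. For the size of the median, dependence on 1 female rat is argued against by a lowest value of 0.103, reached without female control 1. The calls of the lists did depend on single rats, since leaving out any of 20 of the 29 rats ended them. What stays open is an effect of the scent, of handling or of the time between exposure and dissection, each of which may raise these genes and none of which could be separated here.

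Over both sexes, many probes differed between extreme and minimal responders. The array set alone is argued against as the cause of all of them, since 15.1% of the called probes passed with the set as a block. For *Rpl37l1*, *Rpl7* and *Rpl23* the set and the response cannot be told apart, since these probes helped to define the sets. The fall of their median from −1.55 to −0.12 with the block follows from that. Over all 11888 probes, the 8 that defined the sets included, a single draw of simulated set effects with no group effect gave 199 calls without the block. With the block it gave 0, which decides little, since the block fits the same shift that was simulated. A second array set, as strong as the first, that holds the extreme responders alone is argued against, since 0 probes divided the 10 extreme responders of set B from its other 7 rats by the gap that defined the sets (the widest gap was 0.11). In 28 probes these 10 and 7 rats did not overlap, so a weaker technical difference that follows the extreme group and a difference in biology between the responders stay open.

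*Rps9* stood at a high or a low level in each rat, with means of 11.55 and 7.35 on a first probe and 12.49 and 10 on another. The higher level was found in 6 rats (female controls 3 and 5, male controls 1 and 4, male minimal 2 and male extreme 3) and the lower in 23. The array set is argued against as the cause, because 4 of the 6 were in set A and 2 in set B. An inherited difference between rats may give such levels, and the higher level was seen in 4 groups, but the arrays hold no genotype, so this stays open.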

How the results depend on the processing

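The array set fits, the stricter filter, cyclic loess, the variance trend with a robust prior, the residual components and the block without male extreme 4 were chosen after the results were seen. Not run were background correction from the array signals, quantile normalisation without it, median scaling, a filter by detection p and the slide as a block, since the signal columns could not be given to rats and no slide was named. Of 969 values of named genes, 945 kept direction and side of the threshold without the filter on dim probes (24 weaker), 926 with the replicate block (40 weaker, 3 stronger), 920 with array weights (7 weaker, 42 stronger), 959 with cyclic loess and 950 with the variance trend. The set as a block kept 873 (72 weaker, 23 stronger, 1 reversed). No such count is given for set B, which held 1 male minimal responder. Only values past the threshold in the main fit could become weaker, and most of the 969 were not past it. The shares that stayed alike therefore do not tell what share of the calls held. The stricter filter left 684 values and 678 were alike, and each sex fitted alone gave 843 values and 787. Over all left-out rats, 27198 of 28101 values were alike, 774 weaker and 129 stronger. The causes were not tested, except that fewer rats or probes enter some fits. The residual components are orthogonal to the groups, so they leave fold changes as they are and only shrink the residual spread. Signal over background limits the dim probes, which the filter left out.

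Without the filter, exposure over both sexes gave 4 probes. The stricter filter gave 4 for exposure in females, 8 over both sexes and 0 lists for exposure in females. With each sex alone, exposure in females gave 12, extreme against control 180 and minimal against control 1, and in males extreme against minimal and extreme against control gave 0 each. Array weights gave 11 and 2 for exposure in females and males, 697 and 24 for extreme against minimal, 416 for extreme against control in females, 1 and 1 for minimal against control, 25 for exposure over both sexes, 3 for the sex difference in extreme against minimal response and 75 for males against females. Cyclic loess gave 9 for exposure in females. The variance trend gave 6 there, 0 for extreme against minimal response in males and 2 for the sex difference in that response.

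The replicate numbers do not pair the rats: after removing group means, 28 pairs of the same number had a mean correlation of −0.009 (11 over 0.1), and 112 other pairs 0.004 (37 over 0.1). The replicate block gave 0 and 2 for exposure in females and males, 0 for extreme against minimal and 35 for extreme against control in males, 0 for exposure over both sexes and 0 lists for exposure in females, and no other count moved by over 1.5 times.

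The array set as a block gave 26 for exposure in females, 4 for extreme against minimal in males, 189 for extreme against control in females, 6 and 1 for minimal against control, 30 for exposure and 244 for extreme against minimal over both sexes, 4 for the sex difference in the latter, 56 for males against females and 1 list for exposure in females. The agreement of the sexes in extreme against minimal response fell to 0.364. *Actb* reversed to −0.03. Leaving out male extreme 4 as well gave 122, 391 and 68 for exposure, extreme against control and minimal against control in females, 1 for minimal against control in males, 71 and 391 for exposure and extreme against minimal over both sexes, 15 for the sex difference in the latter and 196 for males against females, with *Actb* at −0.09. Set B alone gave 2 for extreme against control in females, and 0 for exposure and extreme against minimal in females, extreme against control in males and the lists for exposure in females. Comparisons that use male minimal responders are not counted in set B, which held 1 of them. As an effect size only, *Cldn11* reversed there to −0.03 for extreme against minimal over both sexes, with that 1 male minimal responder. The unadjusted counts of limma in set B stand in the report. Set A alone gave 1 and 2 for minimal against control in females and males.

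The first residual component gave 15 and 5 for exposure in females and males, 762 and 310 for extreme against minimal, 232 and 464 for extreme against control, 19 and 1 for minimal against control, 23 and 1485 for exposure and extreme against minimal over both sexes, 5 and 4 for the sex differences, 68 for males against females and 1 list. The first 2 components gave, in the same order, 96 and 27, 1090 and 704, 554 and 823, 69 and 1, 83 and 1909, 19 and 20, and 192. Camera with the preset correlation gave 5 and 2 lists for exposure in females and males and 7 and 1 for extreme against minimal, and fry gave 1 in females for the latter.

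Leaving out each rat gave 0 to 21 probes for exposure in females (highest without male extreme 4) and 0 to 3 in males (3 without male extreme 1, 1 without male extreme 5). *Ddit4*, the 1 probe called with all rats, was weaker in 10 of the 29 leave-outs. Extreme against minimal response in females ranged from 222 without female minimal 5 to 616 without male extreme 4. It was 227, 262 and 299 without female extreme 1, 2 and 4, and 279 without female minimal 3. In males it ranged from 0 to 101. Extreme against control in females ranged from 60 without female control 3 to 211 without male extreme 4. It was 183 and 64 without female controls 2 and 4, and 76, 73, 67 and 72 without female extreme 2, 3, 4 and 5. In males it ranged from 6 without male control 4 to 124 without male extreme 5. It was 22 without male control 2 or 3, and 47 and 18 without male extreme 2 and 4. Minimal against control ranged from 0 to 11 in females (11 without male extreme 4, 6 without female control 5, 3 without female minimal 4) and from 0 to 1 in males (1 without female minimal 2). Exposure over both sexes ranged from 0 to 19. Extreme against minimal over both sexes ranged from 609 without male minimal 4 to 1143. The sex differences ranged from 0 to 1 (1 without female control 5) for exposure and from 0 to 4 (4 without male extreme 1, 3 without male minimal 3) for extreme against minimal. Males against females ranged from 18 to 79, the latter without male extreme 4, and gave 48 without female minimal 1. Lists for exposure ranged from 0 to 2 in females and from 0 to 1 in males (1 without male control 3).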

Other observations

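The tests on other splits of the rats were chosen after the results were seen. Several cell type lists are not described above, and none of them passed with an estimated correlation. In minimal responders against controls in females, all 8 GABA receptor genes had a lower value (median −0.13, adjusted p = 0.33), as did 4 of 5 dentate granule cell markers (median −0.23, 0.33). Interneuron markers had a higher value in 12 of 13 (median 0.15, 0.421) and oxidative phosphorylation subunits in 48 of 59 (median 0.10, 0.465). In minimal males against controls, GABA receptors had a median of 0.13 with 6 of 8 higher (0.243), and 1 passed as higher when adjusted over the list alone.

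Markers of tissue next to the hippocampus varied between rats. Choroid plexus markers such as *Ttr* moved together, with a correlation between genes of 0.90, and had a median of −0.42 in males against females, with all 10 lower (adjusted p = 0.941 with an estimated correlation). Between extreme and minimal responders in females, thalamus markers had a median of 0.43 with 6 of 7 higher (0.678), and meningeal and fibroblast markers of 0.11 with 10 of 12 higher (0.781). Astrocyte markers had a median of 0.07 with 10 of 13 higher (0.678), and 6 of 13 microglia markers were higher (0.967). In male extreme against minimal responders, 4 of 13 astrocyte markers passed as higher when adjusted over the list alone (median 0.14, 0.773). No list passed for the difference between array sets A and B (lowest adjusted p = 0.886).

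Random splits of the rats into groups of the same sizes excluded chance in several comparisons. Of 100 splits, the real one included, 1 gave as many probes for extreme against minimal response in females (450, highest other 2) and over both sexes (945, highest other 8), for extreme against control in females (119, highest other 28) and males (74, highest other 6), and for males against females (25, highest other 0). In the remaining comparisons chance was excluded only by the share of splits, with no correction over comparisons, since another split gave as large a result or a larger one. These were extreme against minimal response in males, where 3 of 100 did (9, highest other 15) and the block ended all 9 calls, exposure over both sexes, where 2 did (13, highest other 123), and the lists for exposure in females, where 2 did (2, highest other 2). By the unadjusted counts, 4 of 100 splits gave as many for extreme against minimal response in males (1799) and 6 of 100 for exposure over both sexes (1032), so for exposure over both sexes the unadjusted count does not exclude chance. The real groups of these extreme comparisons were themselves uneven in the array set: the share of set A rats differed by −0.60 for the extreme against minimal response in females, −0.75 for the extreme against minimal response in males and −0.667 for the extreme against minimal response over both sexes. Of the 99 other splits, 20 were at least as uneven in females, with at most 2 calls, and 3 in males, with at most 1. Over both sexes 0 were as uneven, so there the splits without a block exclude chance but not the set. When the set was a block, the splits were made within the sets. Of 21 such splits, the real one included, 1 gave as many for extreme against minimal (388, highest other 0) and extreme against control (189, highest other 1) in females. The same held for extreme against control in males (57, highest other 0). This is the smallest share that 21 splits can give, so a larger effect could not lower it. Of 100 splits within the sets, 1 gave as many for exposure in females (26, highest other 2) and extreme against minimal over both sexes (244, highest other 48).

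Chance was not excluded for the exposure effect in females without a block, where 10 of 100 splits gave as many (1, highest other 152), although 4 of 100 did by the unadjusted count (1208). A real count of 0 is matched by all 100 splits whatever the data, so it says nothing about chance: the exposure effect in males (highest other 250), minimal response against control in females (2) and males (72), the sex difference in the exposure effect (457) and the sex difference in the extreme against minimal response (5). The same holds for the counts of lists in the exposure effect in males (0, highest other 2) and in the extreme against minimal response in females (0, highest other 1) and males (0, highest other 1). By the unadjusted counts, 4 of 100 splits gave as many for minimal response against control in females (1314), 25 for minimal response against control in males (504), 24 for the exposure effect in males (1010), 9 for the sex difference in the exposure effect (1150) and 13 for the sex difference in the extreme against minimal response (932). Splits with 152, 250, 123, 457 and 72 calls point to a structure of the samples. In the split with 152 calls the share of set A rats differed by 0.60 between the groups, and in that with 250 by 0.667, so these splits followed the array set more closely than the real exposure effect in females (−0.30) and exposure effect in males (−0.267) did. With the block the real counts were 26 and 0, and 30 for the exposure effect over both sexes.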
